A study of Strongylocentrotus purpuratus with 7 samples.

How the data were processed

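Libraries were made from polyadenylated RNA, selected in repeated rounds from DNase-treated total RNA, with a barcoded strand-specific SOLiD kit, and were sequenced as single-end reads, per the labels' protocols. Bowtie 0.12.7, a short-read aligner, and HTSeq, which counts reads per gene, are named in the submitters' processing notes. The genome build and the gene annotation are not given in the sources used here. The deposited table has a line per gene model and 7 named columns, and its values are not described further because none was used.

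Samples were grouped by the temperature field of their labels, with 4 at 18 °C and 3 at 12 °C, and by the fields for female and male parent. An additive model of temperature, female parent and male parent on the read counts, an interaction of temperature with female parent, tests of gene lists and a set of alternative settings were planned before the data were examined. None of them was run. Each column has to be tied to a sample by its name. Of the 7 columns with values per library, 0 had a name that occurs anywhere in the sample labels. Assigning them by their order in the table would have been a guess at temperature and parentage, and all 7 columns were left unused. No normalisation, filter or test was therefore applied.

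The column names and the row identifiers of the table were read with Python 3.11.15. The 26428 row identifiers, all of them distinct, were looked up among the gene identifiers, locus tags, symbols, synonyms and accessions of a RefSeq gene table of the species (assembly Spur_5.0), and 0 were found. All 26428 belong to the SPU_ series, and the RefSeq table holds 0 entries of that series. Names of genes are not used here for that reason.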

Results

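Gene expression was measured by RNA sequencing in 7 libraries of gastrula-stage embryos of the purple sea urchin, Strongylocentrotus purpuratus. Gastrulation is the stage at which the embryonic gut forms and the skeleton-forming mesenchyme begins to build the larval skeleton. Embryos of controlled crosses were raised from fertilization to the middle of gastrulation, and 4 libraries came from cultures kept at 18 °C and 3 from cultures kept at 12 °C. The series title gives the question as the genetics of the expression response to temperature stress in a gene network.

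The crosses combined 3 female parents, labelled A, C and D, with 2 male parents, labelled A and D. Not every combination was present among the libraries, because female D occurred only with male A. Female A gave 3 libraries, female C gave 3 and female D gave 1. Male A fathered 3 of the libraries and male D fathered 4. At 18 °C, 2 libraries had female A, 1 had female C and 1 had female D, whereas at 12 °C 1 library had female A and 2 had female C. The female parents were therefore spread unevenly over the temperatures. The male parents were closer to even. At 18 °C, 2 libraries had male A and 2 had male D, and at 12 °C 1 had male A and 2 had male D. Only 2 crosses, female A with male D and female C with male D, were present at both temperatures, each with 1 library per temperature. The samples also carry a culture number. For female A with male D it was 1 at 18 °C and 2 at 12 °C, so that pair differed in culture number as well as temperature. For female C with male D it was 1 at both temperatures. What the culture number stands for is not known here, so an equal number does not show a shared culture. The title of the library with female D writes the female parent as X, and the parent field was followed here.

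The design implies a comparison of 18 °C with 12 °C, comparisons between female parents and between male parents, and a test of whether the temperature response differs between females A and C. The plan already held the last of these to have low power, because the 7 libraries leave little from which to estimate the spread. None of these comparisons was made. The names of the 7 columns of the deposited table match no title or other label of the 7 samples, so the temperature and parents of each column are not known here. No expression value, fold change or test is reported for any gene, and no depth is reported for any library.

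The table lists 26428 gene models, all by identifiers of the SPU_ series. The gene name table used here, built on the Spur_5.0 assembly, holds 0 identifiers of that series, so no gene model was paired with a gene name. Whether the gene models of the table correspond to those of the Spur_5.0 assembly was not examined, and the lack of matches says nothing about it. The 21 gene lists set before the data were examined, which covered chaperones, the germ layers and skeletogenic cells among others, were not applied.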

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

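The values given here are counts of matched names. A looser match that kept only letters and digits and ignored case, a setting chosen after seeing the data, also gave 0 column names in the sample labels and 0 gene identifiers in the name table. For column names it searched only the titles, descriptions, source names and characteristics, whereas the first search covered all label text. This repeat shows nothing about robustness. For the gene identifiers it could not have come out otherwise, because the name table holds 0 identifiers of the SPU_ series. All 7 column names are a shared word with a number, and the labels were not searched for that word alone. The settings chosen before the data were examined were not run, because no comparison was made. They covered normalisation, the filter on low counts, the test, the model terms and leaving out each library in turn. No paired analysis was possible because the columns of the table were not matched to samples.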
